A study of Rattus norvegicus with 19 samples.

How the data were processed

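Spinal dorsal horn RNA of 19 rats was hybridised on 19 two-channel cDNA arrays, with each stimulated rat in Cy3 and a pool of 5 control rats in Cy5, per the labels. The 38 scanner files hold spot intensity values (signal mean, background mean, background median and background SD) that are neither background-corrected nor normalized, per the file headers and the values. They were written by ImaGene 5.1 per the file headers, while the labels name ImaGene 4.2. Spot flags are an other kind of value per the file headers, and their codes are not explained there. The series value table holds a score, the log ratio of Cy3 over Cy5 as processed by the authors. Its direction was found by setting each column against the scanner ratios, while its log base, scale and centring are not given in the sources used here. Its column medians were between 0.001 and 0.052 and its interquartile ranges between 0.93 and 0.95.

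Each array has 12288 spots in 48 subgrids. The 576 spots without an entry in the value table were treated as control spots, which is an inference. Intensities were corrected with normexp (offset 50) on all spots, and log2 Cy3/Cy5 ratios were normalized by loess within each array with control spots at weight 0. There was no scaling between arrays. Spots with flag 1 were left out. A probe was kept when its signal exceeded the background mean by 2 background SD in the same channel on at least 4 arrays, which left 11504 and removed 208. A spot was counted as saturated above 65000, and saturated spots were kept.

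Group means over all 19 arrays were fitted per probe with limma 3.58.1 in R 4.3.3 (lmFit and eBayes, two-sided), with 15 residual and 3.24 prior degrees of freedom, and p was adjusted by Benjamini-Hochberg with a threshold of 0.05. A total of 10 comparisons were made, namely HR against LR at each frequency, their average and their difference, the frequencies within each responder class, and each group against the pool. Random blocks used duplicateCorrelation with statmod 1.5.0. The p-values measure only the spread between these rats, each on 1 array, so it includes labelling, hybridization and slide. The number of arrays limits the precision. The 4 groups shared 1 estimate of the spread per probe, although their spreads were unequal. The median within-group SD in Cy3, over probes of mean log2 intensity over 8, was 0.231 in 2Hz HR and 0.242 in 100Hz HR. It was 0.158 in 2Hz LR and 0.131 in 100Hz LR, so HR comparisons borrow the smaller LR spread. The median standard error of a log2 difference was 0.129 for 2Hz HR against 2Hz LR and 0.122 for 2Hz HR against 100Hz HR. Per array, the median signal over background was 1.81 to 5.92 in Cy3 and 4.51 to 18.4 in Cy5.

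The comparisons, the rule for named genes and 28 gene lists were fixed before the data were examined. The rule took, among probes past the threshold that name 1 gene, are above background on every array of a compared group and keep their direction, those with the largest rise and fall, besides members of the gene lists and a set of opioid, neuropeptide and glial genes. None of the spot names (0) was found in the gene table of the GRCr8 assembly, so the named genes, the gene lists and the tests on them could not be applied. In their place the same rule without gene names gave the 2 largest rises and 2 largest falls of the first comparison.

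The fit was tested on simulated data with the fitted spread of each probe, in which 200 of 11504 probes were changed by a known amount. The simulated spread was equal on all arrays and independent between probes, unlike that of the real arrays. For 2Hz HR against 2Hz LR, 44% were recovered at a log2 change of 0.5, 91.5% at 1 and 99.5% at 2. Alternatives were other background corrections, normalizations, filters and flags, the compared arrays alone, the replicate number, the slide lot, the authors' table and leaving out each array. Array weights, slide runs (5 runs of neighbouring slide numbers), the day of image analysis and leaving out 4 arrays were added after the data had been seen. For the overlap of the control comparisons, unchanged rats were simulated 100 times against a pool of 5 rats with the fitted spread.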

Results

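Gene expression was measured in the spinal dorsal horn of Sprague-Dawley rats 1 hour after 30 min of electroacupuncture, which is electrical stimulation through acupuncture needles, at 2 Hz or 100 Hz. The dorsal horn is the part of the spinal cord that receives pain signals. Rats were grouped by frequency and by the strength of their analgesic response into high responders (HR) and low responders (LR), with 5 rats in 2Hz HR, 4 in 2Hz LR, 5 in 100Hz HR and 5 in 100Hz LR. Each rat had 1 array, labelled with Cy3, and every array carried the same Cy5-labelled pool of RNA from 5 rats that were not stimulated. Of 11712 probes with an entry in the deposited table, 11504 were above background often enough to be tested. The probe IDs give positions on the slide, and the files do not pair them with gene names, so results are given as numbers of probes, with the IDs of 2 probes that rose and 2 that fell.

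The arrays came from 2 slide lots, and signal strength followed the lot. All 9 2Hz arrays and 100Hz HR replicate 1 were on slides of lot 1, where the median Cy3 signal over background lay between 1.81 and 3.25. The other 9 arrays, all from rats stimulated at 100 Hz, were on lot 2, with 4.19 to 5.92. The share of probes above background in Cy3 was 80.7% ± 2.75 (SD, n = 10) in lot 1 and 91.2% ± 2.08 (SD, n = 9) in lot 2. Across probes, which are not independent replicates, the log2 Cy3/Cy5 ratios of pairs of arrays correlated with a median r of 0.668 over 171 pairs and a lowest r of -0.0769. The mean correlation with the other arrays of the group was 0.794 ± 0.0284 (SD, n = 4) in 2Hz LR and 0.805 ± 0.025 (SD, n = 5) in 100Hz LR, against 0.483 ± 0.0413 (SD, n = 5) in 2Hz HR and 0.54 ± 0.123 (SD, n = 5) in 100Hz HR. Within 2Hz HR, replicates 1, 2 and 3 correlated with replicates 4 and 5 at r from 0.179 to 0.558, while replicates 4 and 5 correlated with the 2Hz LR arrays at 0.764 to 0.852.

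**Figure D1:**
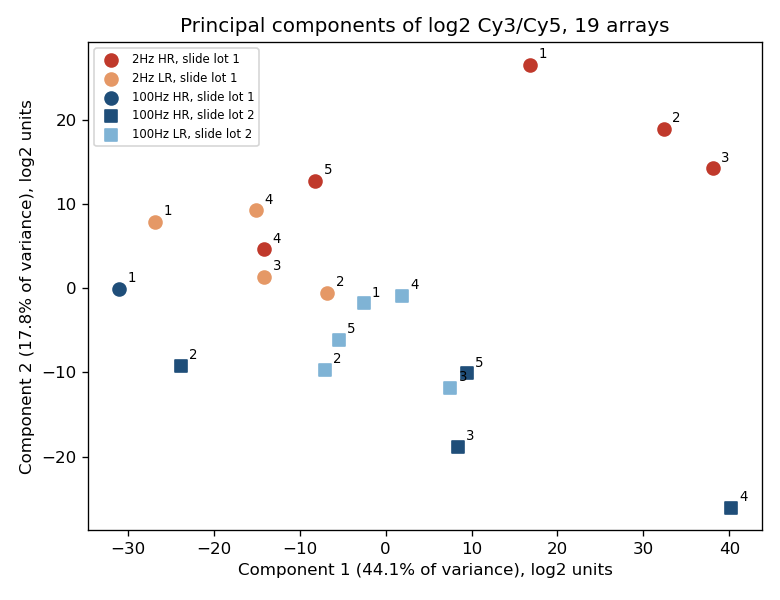
Each point is 1 of 19 arrays, placed by the first and second principal components of its log2 Cy3/Cy5 ratios, which hold 44.1% and 17.8% of the variance, with the replicate number beside it, the group as colour and the slide lot as marker shape. The 2Hz LR and 100Hz LR arrays lie closer to the others of their group than the HR arrays do.

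High and low responders to 2 Hz stimulation were compared to find transcripts that differ with the analgesic response. Between them 33 of 11504 probes differed, of which 25 were higher and 8 lower in 2Hz HR (limma, Benjamini-Hochberg adjusted p under 0.05). The higher probes included 13 with a difference of at least 2-fold, and none of the lower ones reached that size. The 33 called probes were bright, with a median average log2 intensity of 11 against 9.55 over all tested probes. The median log2 ratio to the control pool over the 25 probes was 0.67, 0.69 and 0.55 on 2Hz HR replicates 1, 2 and 3, -0.18 and 0.19 on replicates 4 and 5, and -0.59, -0.87, -0.60 and -0.80 on the 2Hz LR arrays. Probe Sr10Sc02R03C07 had a log2 Cy3/Cy5 ratio of 0.59 ± 0.61 (SD, n = 5) in 2Hz HR and -1.16 ± 0.36 (SD, n = 4) in 2Hz LR, a 3.37-fold difference (log2 difference 1.75, SE 0.33, limma adjusted p = 0.033). Probe Sr08Sc02R03C05 had 0.66 ± 0.51 (SD, n = 5) and -1.06 ± 0.35 (SD, n = 4), a 3.28-fold difference (log2 difference 1.71, SE 0.29, limma adjusted p = 0.033). Probe Sr08Sc02R07C16 was lower in 2Hz HR, at -0.61 ± 0.2 (SD, n = 4 measured of 5) against 0.06 ± 0.19 (SD, n = 4), a log2 difference of -0.67 (SE 0.1, limma adjusted p = 0.0274). Probe Sr07Sc01R10C01 was also lower, at 0.66 ± 0.34 (SD, n = 5) against 1.31 ± 0.092 (SD, n = 4), a log2 difference of -0.65 (SE 0.14, limma adjusted p = 0.0476). In the order given, the calls were lost in 15 of 34, 13 of 34, 12 of 33 and 25 of 34 alternatives. In 9, 7, 7 and 16 of these the difference was no smaller than with all arrays. The 9, 7 and 7 each count the deposited table as no smaller, although its sizes are not comparable, so they are too high by that alternative. The log2 difference of Sr08Sc02R07C16 was -1.69 with subtracted background. In the deposited table, whose log base and scale are not given, the differences were -0.35 for Sr07Sc01R10C01 (limma adjusted p = 0.693) and -1.50 for Sr08Sc02R07C16. These sizes cannot be set against those from the scanner files.

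The count for 2 Hz depended on single arrays and on the processing. It was 0 without 2Hz HR replicate 1 or 3, without 2Hz LR replicate 2, 3 or 4, or without 100Hz LR replicate 5. It was 2 without 2Hz HR replicate 2, 11 without 2Hz LR replicate 1, 5 without 100Hz LR replicate 2, 15 without 100Hz LR replicate 4, 16 without 100Hz LR replicate 1, 17 without 100Hz HR replicate 2 and 21 without 100Hz HR replicate 3. Without 2Hz HR replicate 5 it was 543, and without 2Hz HR replicate 4 it was 1161. No probe passed when the fit used the 2 compared groups alone, or with the replicate number or the run of slide numbers as a fixed term. Nor did any pass within the slide run that held 5 2Hz HR and 2 2Hz LR arrays. None passed without 2Hz HR replicates 1, 2 and 3 and 100Hz HR replicate 4, arrays left out after their ratios had been seen. With median centring of each array 17 probes were higher and 1 lower, with subtracted background 129 and 50, and with array weights 594 and 348. The deposited table had 0 higher and 2 lower, of which 0 were among the 33.

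**Figure D2:**
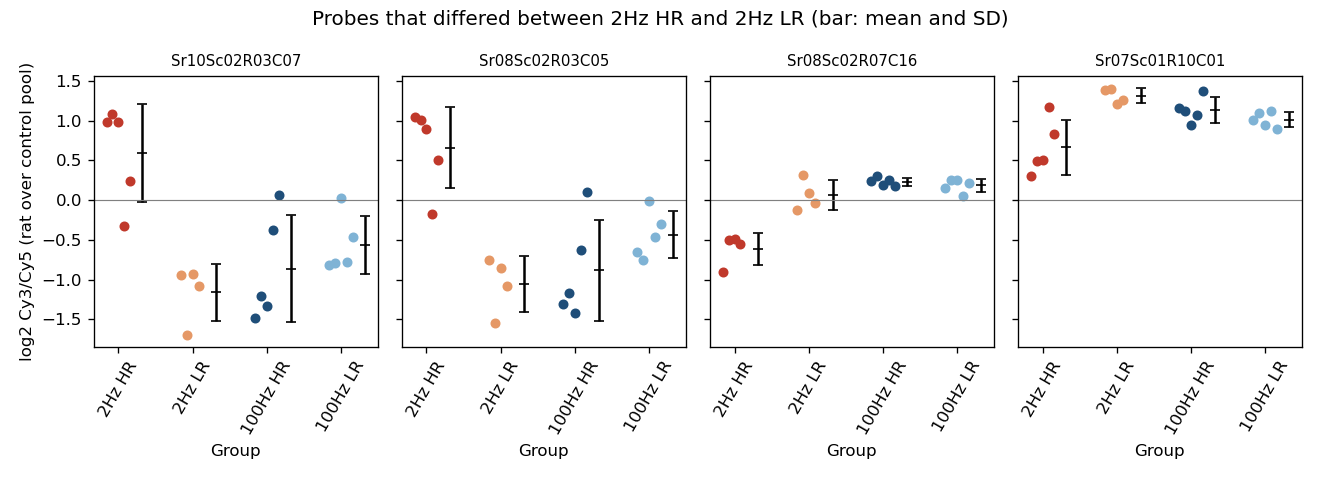
Points are the log2 Cy3/Cy5 ratios of single arrays for the 4 named probes in each group, and black bars give the mean and SD. The first and second probes averaged 0.59 and 0.66 in 2Hz HR, and were below 0 on average in the other 3 groups.

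Between high and low responders to 100 Hz stimulation, limma called 0 of 11503 probes, and 711 had an unadjusted p under 0.05. The count was 1 in the deposited table and 1 with slide runs as a fixed term. The lowest adjusted p was 0.711, and the typical standard error of a log2 difference was 0.122. In simulated data with this spread, 53.5% of 200 probes changed by 0.5 on the log2 scale were recovered. Of those changed by 1, 94.5% were recovered. All simulated arrays spread alike, and independently between probes, while the real 100Hz HR arrays correlated less within their group than the 100Hz LR arrays (0.54 against 0.805). Recovery on the real arrays may differ, so the 0 calls do not exclude large differences. Averaged over both frequencies, the HR and LR groups also differed at 0 probes by limma, with 1291 at an unadjusted p under 0.05. That count was 17 with subtracted background, 12 higher and 5 lower, and 1 each in the deposited table and with slide runs as a fixed term. The difference between HR and LR at 2 Hz, set against that at 100 Hz, passed the threshold for 0 probes in limma, with 1929 at an unadjusted p under 0.05 and a lowest adjusted p of 0.0593. That last count became 713 without 2Hz HR replicate 4 and 37 without 100Hz HR replicate 5. With all arrays it was 52 with subtracted background, 24 with all flagged spots left out, 4 with median centring and 328 with array weights (chosen after seeing the data), so whether any probe passes depends on the processing.

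The frequencies were compared within each responder class. In high responders 1205 of 11503 probes differed, with 653 higher and 552 lower after 2 Hz than after 100 Hz, and 164 higher and 8 lower by at least 2-fold. The median log2 ratio to the control pool over those 164 probes was 1.16, 1.25 and 1.14 on 2Hz HR replicates 1, 2 and 3, but -0.54 and -0.25 on replicates 4 and 5. In low responders 71 of 11504 probes differed, with 37 higher and 34 lower after 2 Hz. The called probes in low responders were dim, with a median average log2 intensity of 7.28 against 9.55 over all tested probes, and none passed when only probes above background in both channels on every array were tested. The split moved with the processing, to 167 higher and 57 lower with median centring, but 119 and 171 with subtracted background, 636 and 1074 with the compared arrays alone, 715 and 988 with array weights, 180 and 334 without 2Hz HR replicates 1, 2 and 3 and 100Hz HR replicate 4, and 4 and 23 in the deposited table.

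Frequency and slide lot overlapped almost fully. With the lot as a fixed term, which only 100Hz HR replicate 1 allows to be separated from frequency, 17 probes differed in high responders, 2 higher and 15 lower, of which 3 were among the 1205. In low responders 7 differed, 1 higher and 6 lower, of which 0 were among the 71. Within lot 1, the 5 2Hz HR arrays against that lone 100Hz array, assumed to vary like the 2Hz HR arrays, gave 3 probes, all lower and 0 of them among the 1205, but with 1 array on one side few calls can be made. In low responders each lot held 1 group only, so no value within a lot can be given. With slide runs as a fixed term 10 differed in high responders, 1 of them among the 1205, and 5 in low responders, 0 of them among the 71. With the replicate number as a block 796 differed in high responders and 25 in low responders. The count for high responders was 185 in the deposited table, 83 higher and 102 lower, and 0 with the compared arrays alone. It was 559, 768 and 668 without 2Hz HR replicate 1, 2 and 3, 648 and 651 without 100Hz HR replicate 2 and 3, and 1827 without 2Hz HR replicate 4. Without 2Hz HR replicates 1, 2 and 3 and 100Hz HR replicate 4, arrays left out after their ratios had been seen, it was 100, 12 higher and 88 lower, of which 45 were among the 1205. The count for low responders was 23, 22 and 16 without 2Hz LR replicate 2, 3 and 4, and 26, 22, 20, 20 and 22 without 100Hz LR replicate 1, 2, 3, 4 and 5. Without 100Hz HR replicate 1 it was 264.

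**Figure D3:**
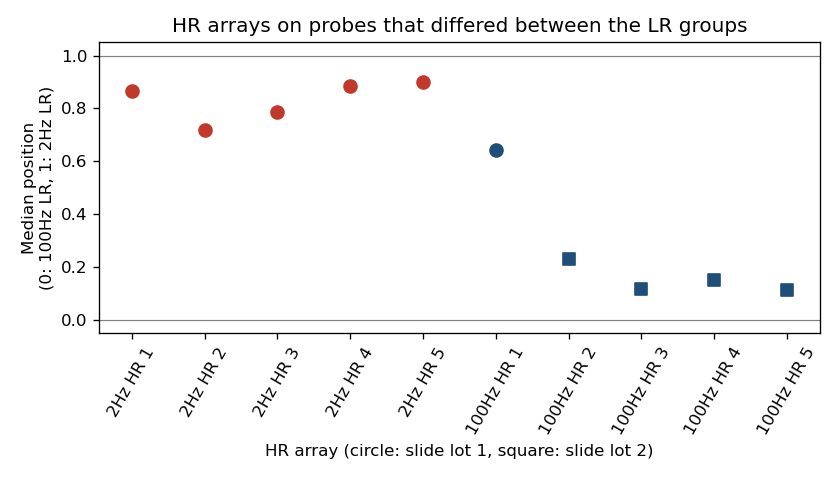
Each marker is 1 HR array, placed by its median position over the 71 probes that differed between the LR groups, on a scale where 0 is the 100Hz LR mean and 1 the 2Hz LR mean. 100Hz HR replicate 1, on a lot 1 slide, lies at 0.641, between the other 100Hz HR arrays (0.115 to 0.229) and the 2Hz HR arrays (0.72 to 0.9). The HR arrays entered the spread used to call these 71 probes. On 1710 probes called from the LR arrays alone, 100Hz HR replicate 1 lay at 1.01. The other 100Hz HR arrays then lay at -0.389 to 0.584 and the 2Hz HR arrays at -0.0124 to 1.01.

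Each group was also compared with the control pool, by testing the mean log2 Cy3/Cy5 ratio against 0. In 2Hz HR 2306 probes were higher and 2619 lower than in the pool, in 2Hz LR 2999 and 3228, in 100Hz HR 2415 and 2734, and in 100Hz LR 2305 and 2480 (limma, adjusted p under 0.05). The deposited table gave fewer and more often higher probes, at 1123 and 1077, 1152 and 1051, 1007 and 854, and 1208 and 1073 in the same order. With the slide lot as a fixed term 1943, 2274, 4912 and 3838 probes in all differed, in the same order. With slide runs as a fixed term it was 603, 1898, 2657 and 2599, and with the arrays of each group alone 3067, 6536, 3259 and 7183. In the lot and run fits each group mean was moved to that of an average slide. The lot effect used for this rests on 100Hz HR replicate 1 against its group. Fewer calls there need not mean that the lot explains the others. Most of the differences in the fit of all arrays were small, with a median absolute log2 ratio of 0.35 to 0.43 among the called probes. At least 2-fold differences were more often reductions, with 3 higher and 90 lower in 2Hz HR, 54 and 322 in 2Hz LR, 10 and 225 in 100Hz HR, and 10 and 131 in 100Hz LR. All 4 groups were called in the same direction at 1049 higher and 1232 lower probes, and 37 probes were at least 2-fold lower in all 4. As the pool has no array of its own and no dyes were swapped, these counts leave out the spread between control rats and include any dye bias of a probe.

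The group means against the pool correlated across probes with r from 0.631 (2Hz HR with 100Hz HR) to 0.896 (100Hz HR with 100Hz LR). Unchanged groups simulated against a pool of 5 rats gave 0.469 to 0.499. The observed covariances were 0.07 to 0.134, against 0.0143 to 0.0144 in the simulation, which holds no dye bias. For 100Hz HR and 100Hz LR, 1725 higher and 1961 lower probes were shared, where independent lists would share 483.9 and 589.4, and unchanged groups simulated against 1 pool shared 3.56 and 3.22 on average. Neither value holds dye bias. The pool cannot be divided, so part of the excess may come from it. With the mean of the 4 groups subtracted, 1385 probes stood out in 2Hz HR, 2 in 2Hz LR, 0 in 100Hz HR and 46 in 100Hz LR. The 2Hz HR mean joins unlike arrays, as replicates 1, 2 and 3 correlated with replicates 4 and 5 at only 0.179 to 0.558.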

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

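The tests of spread, slide lot and control pool were chosen after the results were seen, while the counts of other splits of the arrays were planned.

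Array-level measures and the named probes were searched for arrays far from the rest of their group, over 52 groups of values, of which chance gives about 1 in 20. The search found 1, the Cy3 deviation from the median profile of 2Hz LR replicate 3, at 0.159 against 0.237 for the nearest array of the group. Spots without an entry in the value table, 372 of them above background, take no part in the comparisons. For this count they were normalized in a separate run in which they entered the loess, and were fitted and adjusted alone. Of them 31 (8.33%) differed between 2Hz HR and 100Hz HR and 29 (7.80%) between 2Hz LR and 100Hz LR. Of the tested probes, normalized with these spots at weight 0, 10.5% and 0.617% did. In the comparisons of HR with LR 0 differed. Against the pool 157 (42.2%) differed in 2Hz HR, 153 (41.1%) in 2Hz LR, 110 (29.6%) in 100Hz HR and 135 (36.3%) in 100Hz LR, where 41.6% to 54.1% of the tested probes did. What these spots carry is not known, so they do not settle dye bias or slide lot.

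The 2Hz HR arrays spread more than the 2Hz LR arrays. The ratio of within-group spreads (2Hz HR over 2Hz LR) was 1.01 in Cy5 but 1.46 in Cy3. With any 1 array left out it was 0.946 to 1.17 in Cy5 and 1.36 to 1.67 in Cy3. This argues against a slide or hybridization cause that acts alike on both dyes. It also argues against a cause in the control pool, which was in Cy5 on every array. Weak Cy3 signal on 1 array was not decided. The array where it was lowest, replicate 1, had the highest mean correlation of its group (0.537). Leaving it out only lowers the mean, to 0.446, by arithmetic. 2Hz HR replicates 1, 2 and 3 had a Cy5 signal over background of 4.51, 6.61 and 7.16, 7, 9 and 12 saturated spots in Cy3, 0 in Cy5 and slopes of 0.568, 0.396 and 0.329 on the mean of the other arrays, while the rest of lot 1 had a signal of 8.08 to 9.89, 0 saturated in Cy3, 1 to 15 in Cy5 and slopes of 1.14 to 1.46. A slide or hybridization that acts unequally on the dyes, RNA quality, Cy3 labelling or scanning and differences between the rats themselves were not tested and stay open.

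The slide lot, or another step that went with the image folder, is a candidate explanation for the frequency differences in low responders. On 1710 probes called from the LR arrays alone, 100Hz HR replicate 1, which is on a slide of the 2Hz lot, lay 2.04 times the way from the mean of the other 100Hz HR arrays to that of the 2Hz HR arrays. That distance is about as large as the spread, with means of 0.00939 (SD 0.419, n = 4) and 0.498 (SD 0.44, n = 5) on a scale where 0 is 100Hz LR and 1 is 2Hz LR. 2Hz HR replicate 3, on lot 1, lay at -0.0124 and 100Hz HR replicate 2, on lot 2, at 0.584. In low responders frequency and lot cannot be told apart, since each lot holds 1 group only.

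The ratios to the control pool shared by all groups had a mean covariance between groups of 0.103, against at most 0.0155 in simulations of the pool. A response to stimulation, differences between control rats beyond that model and dye bias of the probes cannot be told apart, as every array has the same pool in the same dye.

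Of 100 splits of the 2Hz arrays, the real one included here and below, 5 gave as many probes as the real 33, with 1152 in the highest other. Chance cannot be excluded, and such a split points to a structure of the samples. Splits of the LR arrays gave as many probes as the real 71 in 1 of 100, which is the real split, with 2 in the highest other. That is under the 5 in 100 set beforehand, so a random split seldom gives as many, but the real split follows the lot. In high responders 4 of 100 splits gave as many as the real 1205, just under the 5 in 100 set beforehand, but with 3795 in the highest other, so a structure of the samples other than frequency is not excluded. For the comparisons without calls the count of splits decides nothing, since any split gives at least the real 0 (100 of 100), with highest others of 6 for 100Hz HR against 100Hz LR, 1862 for the average over frequencies and 15 for the difference between frequencies.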

How the results depend on the processing

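Leaving out 4 arrays, array weights, slide runs and the day of image analysis were chosen after seeing the data. So were fits within a slide lot or run. Causes of changed counts were not tested, and some settings also held fewer arrays or probes. Leaving out 1 array in turn gave 0 to 1161 probes for 2Hz HR against 2Hz LR (33 with all arrays), 0 to 713 for the difference between frequencies (0), 559 to 1827 for 2Hz HR against 100Hz HR (1205) and 16 to 264 for 2Hz LR against 100Hz LR (71). The other counts stayed within 1.5 times. Without background correction 2Hz HR against 2Hz LR had 16. With subtracted background it had 179, the responder average 17, the difference between frequencies 52 and 2Hz LR against 100Hz LR 290. Median centring gave 18, 4 for the difference between frequencies and 224 for the LR groups. The strict filter gave 0 for the LR groups, with fewer probes tested. Leaving out all flagged spots gave 24 for the difference between frequencies and 5 for the LR groups. With only the compared arrays, both 2Hz HR against 2Hz LR and 2Hz HR against 100Hz HR had 0, the LR groups 1710, and against the pool 2Hz HR had 3067, 100Hz HR 3259 and 100Hz LR 7183. The replicate number as a block gave 0 for 2Hz HR against 2Hz LR, 796 for the HR groups and 25 for the LR groups, and changed no other count by over 1.5 times. The rats were taken to share only a number, which the values do not settle. In their deviations from group means 13 of 27 same-numbered pairs correlated over 0.1 (median r 0.0912, lowest -0.613). The median was -0.0207 for pairs of different number in different groups. Of 19 arrays, 6 correlated best with their own number. By the numbers of the matching columns of the deposited table these were 8 of 27 (median r -0.0477, lowest -0.649) and 2 of 19, and the block was not fitted with those numbers. The slide lot as a fixed term gave 17 for the HR groups, 7 for the LR groups, and 1943 for 2Hz HR and 2274 for 2Hz LR against the pool. A random block on a further digit of the slide barcode, which divides lot 2, gave 13 for the LR groups. Without the 100Hz HR array on a slide of the 2Hz lot the LR groups had 264. The deposited table gave 2 for 2Hz HR against 2Hz LR, 1 for 100Hz HR against 100Hz LR, 1 for the responder average, 185 for the HR groups, 27 for the LR groups, and 2200, 2203, 1861 and 2281 for 2Hz HR, 2Hz LR, 100Hz HR and 100Hz LR against the pool. With the mean of the groups subtracted, these 4 had 1385, 2, 0 and 46. Without the 4 arrays, 2Hz HR against 2Hz LR had 0, the HR groups 100 and the LR groups 514. Array weights gave 942 for 2Hz HR against 2Hz LR, 328 for the difference between frequencies, 1703 for the LR groups and 7583 for 100Hz LR against the pool. Slide runs as a fixed term gave 0 for 2Hz HR against 2Hz LR, 1 for 100Hz HR against 100Hz LR, 1 for the responder average, 10 for the HR groups, 5 for the LR groups, and 603, 1898, 2657 and 2599 for the groups against the pool in the order above. The day of image analysis as a random block gave 24 for the LR groups. Within a slide run 2Hz HR against 2Hz LR had 0, and within lot 1 the HR groups had 3. Aquantile scaling leaves log ratios as they are by construction. The 4 named probes lost the call in 15 of 34 (Sr10Sc02R03C07), 13 of 34 (Sr08Sc02R03C05), 12 of 33 (Sr08Sc02R07C16) and 25 of 34 (Sr07Sc01R10C01) alternatives, leaving out Aquantile and a repeat of the fit without 100Hz HR replicate 1. With the compared arrays alone the sizes were as with all arrays by construction. The same holds with the slide lot as a fixed term or with a 100Hz array left out. With slide runs as a fixed term the sizes were slightly larger, and the same as within the slide run. Without the 4 arrays Sr10Sc02R03C07 fell from 1.75 to 1.12 (limma adjusted p = 0.899) and Sr07Sc01R10C01 was -0.31 in place of -0.65 (0.914), over their ranges of 0.00414 to 0.899 and 0.00283 to 0.914. Sr08Sc02R07C16 was -1.69 with subtracted background, in place of -0.67. In the deposited table, whose log base and scale are not given, Sr07Sc01R10C01 was -0.35 (limma adjusted p = 0.693) and Sr08Sc02R07C16 was -1.50. The alternatives on gene lists (estimated correlation, fry, slide lot, probes per gene) were not run, as no probe has a gene name. Lower signal over background in lot 1 limits what dim probes can show in the 2Hz groups.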

Other observations

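Replicate numbers did not identify the same array in the value table and the scanner files. By log ratios 14 of 19 table columns were closest to another array of their own group, and by the match of blank cells with spots flagged in the scanner files also 14. Both measures picked the same array for 18 columns. The log ratios of a column correlated with those of its closest array at only 0.29 to 0.652. With its own array they correlated at 0.176 to 0.649. The correlation of blank cells with flags was 0.82 to 0.895 for the picked arrays, which were 19 different ones, and ordered by them the slide numbers ascended in all 4 groups, against 1 group in the order of the scanner files. All 19 columns were closest to an array of their own group, so the group means are not affected, while results that name a replicate refer to the scanner files.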
